A study of Drosophila melanogaster with 10 samples.

How the data were processed

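RNA-seq of larval brains of the third instar was compared between 4 libraries labelled vostok and 4 control libraries, of 10 samples in the series. Per the labels' protocols, whole brains were dissected, total RNA was taken up in Trizol and libraries were made with a directional kit. The 2 vostok Micro-C libraries were not analysed here. The deposited table holds estimated counts per gene, not scaled between libraries, with 1 column per library. Its name gives salmon as the quantifier, and its values are fractional. BWA and the build dm6 are named per the submitters' processing notes, without a statement of which assay they were used for. The version of salmon, the annotation release and the strand setting are not given in the sources used here. An aligner or quantifier that divides reads between similar sequences moves counts between paralogs and pseudogenes, so such genes are marked as uncertain.

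Of 24278 rows, 17895 were genes, 5898 transposable element or repeat entries and 485 other entries. Gene rows took 99.3% to 99.5% of each library's counts; element rows entered neither the library sizes nor the main test. The libraries held 57613848 to 81796126 estimated counts, at which 3 counts correspond to 0.0371 to 0.0519 CPM. Reads carry no molecular identifiers, so this floor covers counting error only. Ribosomal RNA genes took 0.797% to 2.85% of counts, except for 8.11% in vostok replicate 3. The file pairs identifiers with symbols, and 17855 identifiers were found in a table of gene names.

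Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr at its defaults, which left 10749 genes, scaled by TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust) in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes of tested genes. Gene lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Of 36 lists 35 could be tested; the list of control strain markers holds only y and w. Library means of lists were compared by exact permutation tests, two-sided, which cannot go below 0.0286 for 4 against 4. The lists cover architectural proteins, Polycomb group, Hox genes, neuronal adhesion, channels, receptors, peptides and synapses, progenitors, E(spl) complex, identity factors, glia, cell cycle, stress, immunity, detoxification, ecdysone response, clock, germline, ribosome, respiration, male-specific RNAs and markers of fat body, hemocytes, muscle, imaginal discs, ring gland, salivary gland, cuticle, gut and chemosensation.

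Gene positions came from the RefSeq annotation of Release 6, the assembly that dm6 names, for 10734 of the tested genes, 10698 of them on the main arms. Arms and the surroundings of CG11504 were compared with Fisher's exact test, and neighbouring pairs with 10000 shuffles of the calls within arms. Genes named in the text follow a rule set before the data were examined: CG11504; among genes past the threshold with separate groups and at least 5 CPM in the higher group, the 8 largest increases and 8 largest decreases, then 4 of each direction with the smallest p; up to 3 called members per list, or up to 2 abundant members of a list with none; y and w; and 2 tested genes on each side of CG11504. Repeat numbers are shared by the groups; whether they pair the libraries was checked from the correlation of deviations.

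The test was tried on simulated counts made from these libraries' means, with 10592 genes in the step. For vostok against control it recovered 37.9%, 66.7% and 81.5% of genes changed 1.5-fold, 2-fold and 4-fold, and 3.94% of its calls were false. The simulation changed only 66, 66 and 65 genes at these folds and drew each gene independently. In these data far more genes were called and lists moved together between libraries, so these figures need not hold here. Alternatives were RLE, upper quartile or no scaling factors, no or a stricter count filter, DESeq2 1.42.0, limma voom with and without quality weights, a replicate block, each library left out, glmTreat against a 1.2-fold change and an adjusted p below 0.01. Alternatives added after the data were seen left out ribosomal and mitochondrial RNA genes, used the hemocyte list mean as a covariate, left out control libraries 1 and 3, took neighbours at least 1 kb apart, and summed transposable element entries per family. Figures were drawn with matplotlib 3.10.9.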

Results

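Whole brains of Drosophila melanogaster larvae of the third instar were profiled by bulk RNA-seq in 8 libraries, of which 4 carried the label vostok, a mutant of CG11504, and 4 came from control larvae whose library names begin with yw. The series states that the mutant was examined for chromatin organization and transcription, so the comparison asked which RNAs differed between the mutant and control brain. Its 2 vostok Micro-C libraries, which map contacts along chromosomes, were not analysed here. The RNA-seq libraries held 57613848 to 81796126 estimated counts each. The labels do not state that the 4 repeats of a group came from separate pools of animals. The p-values therefore measure the spread between these libraries, which may be technical. Levels are given as mean CPM, counts scaled to a common library size, ± SD over the 4 libraries of a group, and log2 fold changes (vostok over control) ± SE with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test.

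CG11504 RNA was not lower in the vostok libraries. The gene (FBgn0039733; Release 6, chromosome 3R, 29997900 to 29999755) was at 60.1 ± 4.99 (control) and 73.6 ± 1.93 CPM (vostok), with each vostok library above each control library (log2 fold change 0.29 ± 0.06, edgeR adjusted p = 0.0143). That call was lost without vostok replicate 3 (adjusted p = 0.0531). The allele is not described in the labels, so this RNA level does not check which libraries are mutant, and each direction given here rests on the labels. The pigment gene y (FBgn0004034; X, 356509 to 361245) separated the groups: it was at 0.846 ± 0.136 (control) and 123 ± 19.6 CPM (vostok) (log2 fold change 7.18 ± 0.18, adjusted p = 1.98e-06). The eye colour gene w was at 3.43 ± 0.591 (control) and 2.08 ± 1.33 CPM (vostok) and did not pass the test (adjusted p = 0.228). Of the tested genes beside CG11504, Sas-6 (15.3 ± 0.453 (control) and 16.8 ± 1.0 CPM (vostok), adjusted p = 0.124), CG15525 (17.2 ± 1.16 (control) and 18.9 ± 1.15 CPM (vostok), adjusted p = 0.158) and Tace (106 ± 31.3 (control) and 138 ± 4.73 CPM (vostok), adjusted p = 0.142) did not pass. Tace passed without control replicate 2 (adjusted p = 0.0108). Nph was lower at 151 ± 17.1 (control) and 126 ± 5.23 CPM (vostok) (log2 fold change -0.26 ± 0.08, adjusted p = 0.0485). Its call was lost when any of 6 libraries was left out (highest adjusted p 0.123, vostok replicate 1 left out) and when the scaling was changed.

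**Figure D1:**
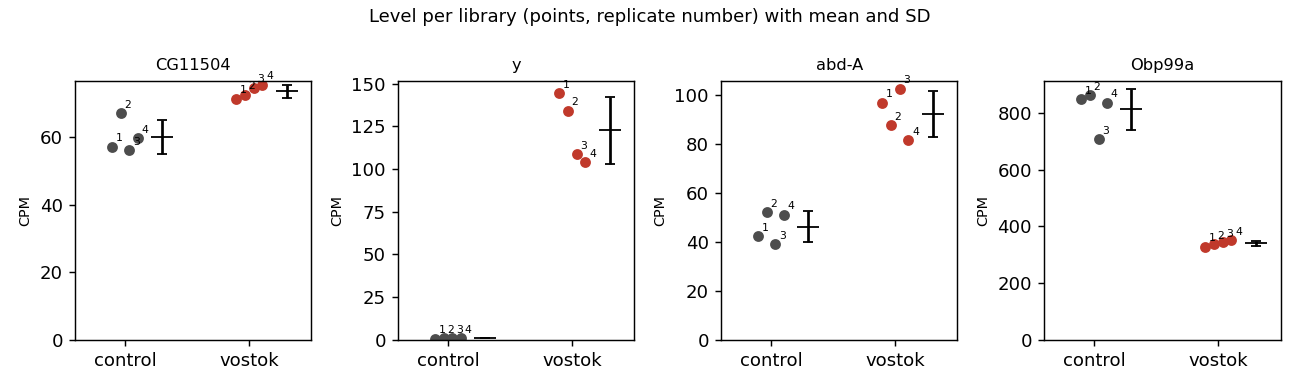
CPM of CG11504, y, abd-A and Obp99a in each library (vertical axis from 0; points are libraries, numbered by replicate; bars to the right are the mean ± SD of 4 libraries). The 4 vostok libraries lie above the 4 control libraries for CG11504, y and abd-A and below them for Obp99a.

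Of 10749 genes tested, 3040 (28.3%) differed at an adjusted p below 0.05. In vostok libraries 1299 were higher and 1741 lower. This balance was not stable. It turned with glmTreat against a 1.2-fold change (751 higher, 634 lower) and at an adjusted p below 0.01 (602 and 455). With DESeq2 it did not turn (2010 and 2320). At least 2-fold changes were seen for 1233 genes, 684 higher and 549 lower, while 1255 of the changed genes moved by less than 1.5-fold. The levels of 3572 genes (33.2%) did not overlap between the groups, against the 2.86% that chance gives for 4 against 4. The first principal component, with 61.7% of the variance, separated the groups. On it control replicate 2 lay closest to the vostok libraries (-20.5, against -46.4 to -66 for the other control libraries). The count depended on single libraries: it was 5333 without control replicate 2, 1740 without control replicate 3, and 1934, 1521, 1538 and 1822 without vostok replicates 1, 2, 3 and 4. The mean log2 CPM of the hemocyte list differed widely between libraries (3.73 to 7.75 in control and 2.12 to 5.20 in vostok libraries). With that mean as a covariate, an alternative added after the data were seen, 1019 genes differed. The group average of this mean was 6.11 in control and 3.87 in vostok libraries. The covariate thus overlaps with genotype and can take up part of a genotype difference. Calls lost with it, here and below, do not show that blood cells caused them.

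The largest increases included genes almost silent in control brains. The pseudogene CR43215 (FBgn0262851) had 0 counts in each control library and 7.89 ± 0.617 CPM in vostok libraries, which is at least 182-fold higher against a floor of 3 counts per library (mean 0.0433 CPM over the control libraries). The adjacent pseudogene CR43216 moved the other way, from 7.78 ± 3.88 (control) to 0.0173 ± 0.0346 CPM (vostok). Together they had about the same level in both groups, so the fold of CR43215 alone is uncertain. CG18278 was at 0.0217 ± 0.0148 (control) and 17 ± 1.36 CPM (vostok) (edgeR adjusted p = 3.76e-06). The cytochrome P450 gene Cyp6a17 was at 0.0303 ± 0.0294 (control) and 13.3 ± 1.71 CPM (vostok) (adjusted p = 3.9e-05), and lncRNA:CR40469 at 0.86 ± 0.103 (control) and 329 ± 129 CPM (vostok) (adjusted p = 1.32e-05). CG12607 was at 0.0263 ± 0.0278 (control) and 5.46 ± 0.603 CPM (vostok). The control means of CG18278, Cyp6a17 and CG12607 rest on 6, 8 and 7 counts over the 4 libraries and lie under that floor, so no fold is given. The genes sordd2, y and CG43389 had log2 fold changes of 7.35 ± 0.24, 7.18 ± 0.18 and 6.66 ± 0.64, with vostok levels of 30.6 ± 0.938, 123 ± 19.6 and 8.29 ± 2.16 CPM. Among genes with the smallest p, CG17186 was at 8.53 ± 0.691 (control) and 45.1 ± 2.93 CPM (vostok) (log2 fold change 2.40 ± 0.08, adjusted p = 3.76e-06). Crg-1 (6.10 ± 0.22), lncRNA:CR43700 (4.80 ± 0.17) and CG15824 (5.04 ± 0.19) followed, as log2 fold changes. Each of these calls held with any 1 library left out.

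The largest decreases took genes with moderate control levels to nearly none. The neighbouring cytochrome P450 genes Cyp4p2 (2R, 9237512 to 9239831) and Cyp4p1 (2R, 9240041 to 9242139) were at 51.3 ± 15.7 and 9.64 ± 2.14 CPM in control libraries and at 0.127 ± 0.0461 and 0.0333 ± 0.0306 CPM in vostok libraries (edgeR adjusted p = 8.87e-06 and 7.75e-05). The pseudogene CR43216, beside CR43215 on X, was lower (7.78 ± 3.88 (control) and 0.0173 ± 0.0346 CPM (vostok), adjusted p = 5.19e-04). The pseudogene CR40190 had a log2 fold change of -7.87 ± 0.40, and CR42653, another, was at 8.44 ± 3.49 (control) and 0.0402 ± 0.0805 CPM (vostok). Of the family of near-identical sperm dynein genes, Sdic2 was at 20.6 ± 1.21 (control) and 0.151 ± 0.205 CPM (vostok) and Sdic3 at 6.24 ± 1.73 (control) and 0.0208 ± 0.0416 CPM (vostok). The antisense RNA asRNA:CR45131 was at 6.28 ± 1.26 (control) and 0.0457 ± 0.0365 CPM (vostok). The vostok means of CR43216, Sdic3, Cyp4p1, CR42653 and asRNA:CR45131 rest on 4, 5, 9, 13 and 12 counts over the 4 libraries, under the floor of vostok libraries (0.0458 CPM), so no fold is given for them. That of Sdic2 rests on 37 counts, and without 1 library its log2 fold change was -8.55 to -6.74. Values of CR43215 and CR43216, the Sdic copies, CR40190 and CR42653, and the Cyp4p pair are uncertain, because counting can divide reads between similar copies. The value of the antisense RNA is uncertain too, since how the counting used strand is not given in the sources used here. Among genes with the smallest p, the ionotropic receptor Ir76a was at 17.5 ± 2.96 (control) and 0.411 ± 0.0582 CPM (vostok) (log2 fold change -5.42 ± 0.18, adjusted p = 3.76e-06). Acbp2, an acyl-CoA-binding protein, was at 23 ± 3.9 (control) and 1.31 ± 0.0967 CPM (vostok) (adjusted p = 3.76e-06). CG34232 (-1.66 ± 0.08) and CkIIalpha-i3 (-1.76 ± 0.09) fell less. Each of these calls held with any 1 library left out.

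Gene lists fixed before the data were examined were tested with camera, which passed 19 of 35 lists, 12 in the higher and 7 in the lower direction. None passed with an estimated correlation (smallest adjusted p = 0.534), and 13 of the 35 splits of the 8 libraries into 4 and 4, the real one included, passed at least 19 lists. In the beat and side, gut, hemocyte, imaginal disc, respiratory, cell cycle and E(spl) lists, 0 members passed edgeR's test in the less frequent direction, and 0 did so at an unadjusted p below 0.05 or with DESeq2. The cuticle, gut and chemosensory lists were among those with a large share of members called. Most of their tested members were at low levels. Whether brain cells express these genes was not tested. In the list of cuticle proteins and chitin deacetylases, 27 of 62 tested members were higher and 4 lower (31 higher and 4 lower adjusted over the list alone; median log2 fold change 1.14). The camera adjusted p was 1.8e-06, and the adjusted p with an estimated correlation 0.534. Cpr65Ec was at 0.735 ± 0.235 (control) and 8.26 ± 0.772 CPM (vostok) (edgeR adjusted p = 1.07e-04) and Cpr49Ae at 0.0381 ± 0.0198 (control) and 0.825 ± 0.189 CPM (vostok) (adjusted p = 2.75e-04). Of the digestive enzymes, 5 of 10 tested members were higher and 0 lower (6 higher and 0 lower adjusted over the list alone; median 2.32). Its camera adjusted p was 0.00134, and its adjusted p with an estimated correlation 0.534. The amylase genes, a pair of near-identical copies whose values are uncertain, were called: Amy-p at 1.18 ± 0.351 (control) and 5.71 ± 0.277 CPM (vostok) and Amy-d at 0.357 ± 0.135 (control) and 2.09 ± 0.271 CPM (vostok). Among chemoreceptors and odorant-binding proteins 18 of 56 tested members were higher and 8 lower (18 higher and 8 lower adjusted over the list alone; median 0.55). Its camera adjusted p was 0.00438, and its adjusted p with an estimated correlation 0.534. Gr61a, a gustatory receptor, was at 1.18 ± 0.152 (control) and 4.93 ± 0.552 CPM (vostok) (adjusted p = 1.42e-04), whereas Obp99a was at 814 ± 71.8 (control) and 341 ± 9.51 CPM (vostok) (adjusted p = 3.94e-05). Of the 82 members of these 3 lists under 1 CPM over all libraries 40 were higher and 4 lower (90.9% of calls higher). Among other tested genes under 1 CPM 442 were higher and 103 lower (81.1%). The file holds 124 cuticle, 40 gut and 236 chemoreceptor genes, so that counts and medians cover only those that passed the filter, which favours silent genes that are high in 1 group. In these 3 lists fry, which tests whether members move one way on balance, gave adjusted p = 0.00335, 0.00172 and 0.00172. Their library means did not overlap between the groups (exact permutation p = 0.0286 for each list, the smallest possible, not adjusted over lists). The chemoreceptor list turned under the stricter filter on low counts, which left 13 members: 2 were higher and 5 lower, with a median of -0.33 (adjusted p = 0.0747). Its call was also lost with the hemocyte covariate (adjusted p = 0.15). When control replicates 1 to 4 and then vostok replicates 1 to 4 were left out in turn, cuticle genes had 22 to 30 higher and 2, 7, 2, 2, 4, 1, 1 and 6 lower. Gut genes had 6, 8, 5, 7, 5, 7, 5 and 5 higher and 0 lower each time. Chemoreceptor genes had 16 to 26 higher and 6 to 11 lower. The stricter filter gave 9 higher and 1 lower of 23 (cuticle), 2 higher of 3 (gut) and 2 higher and 5 lower of 13 (chemoreceptor). The hemocyte covariate gave 1 lower (cuticle) and 3 higher (gut). Leaving out both control libraries 1 and 3 gave 1 lower of 69 (cuticle). Here and below, a list or direction not given for these alternatives may still have had calls.

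Neuronal surface and signalling genes had higher medians in vostok libraries, but few members passed gene by gene. Of the beat and side genes 2 of 22 tested members were higher and 0 lower, of the dpr and DIP genes 5 of 32 higher and 1 lower, and of axon guidance genes 7 of 57 higher and 3 lower. Median log2 fold changes were 0.53, 0.56 and 0.35 (camera adjusted p = 7.82e-04, 7.34e-05 and 0.00147). Ligand-gated channels had 4 higher and 1 lower of 29 (median 0.59, camera adjusted p = 5.78e-04), and voltage-gated and leak channels 2 higher of 28 (median 0.46, 0.00572). Of 22 G protein-coupled transmitter receptors none passed edgeR's test alone (median 0.62, 7.82e-04), against 9 higher at an unadjusted p below 0.05 and 7 higher with DESeq2. Of 31 genes of synapses and mature neurons 1 was higher (median 0.37, 0.00444). Each of these 7 lists had an adjusted p = 0.677 with an estimated correlation. Adjusted over the list alone, 0, 5, 6, 4, 0, 0 and 0 of their members were higher, in that order, and 0, 1, 3, 0, 0, 0 and 0 lower. Without control replicates 1 to 4 and then vostok replicates 1 to 4 in turn, beat and side genes had 1, 18, 0, 2, 1, 0, 0 and 1 higher and 0 lower each time. The dpr and DIP genes had 2, 29, 2, 5, 2, 2, 2 and 2 higher and 1 lower each time. Axon guidance genes had 6, 32, 4, 5, 5, 4, 4 and 5 higher and 2, 5, 1, 2, 3, 1, 1 and 1 lower. Ligand-gated channel genes had 4, 23, 4, 4, 4, 4, 4 and 4 higher and 0, 1, 0, 0, 0, 0, 0 and 0 lower. Voltage-gated and leak channel genes had 1, 21, 0, 1, 1, 0, 0 and 0 higher and 0, 1, 0, 0, 0, 0, 0 and 1 lower. G protein-coupled receptor genes had 0, 21, 0, 0, 0, 0, 0 and 0 higher and 0 lower each time. Synapse and mature neuron genes had 1, 19, 0, 1, 1, 0, 0 and 0 higher and 0 lower each time. Scaled by library totals alone, 0 ligand-gated channel genes were lower. Under the stricter filter the calls were 2 higher and 0 lower of 24 (ligand-gated channel) and 1 higher of 27 (voltage-gated and leak channel). Fitted with the hemocyte covariate, the calls were 0 higher (beat and side), 1 higher (dpr and DIP), 4 higher and 1 lower (axon guidance), 2 higher and 0 lower (ligand-gated channel), 0 higher (voltage-gated and leak channel) and 0 higher (synapse and mature neuron). Without both control libraries 1 and 3 there were 3 higher and 0 lower of 30 (ligand-gated channel). Voltage-gated and leak channel genes then had 0 higher, and synapse and mature neuron genes 1 lower. These lists had the most higher genes without control replicate 2.

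Named members went both ways. The adhesion genes beat-IV (39.9 ± 13.9 (control) and 77.6 ± 3.5 CPM (vostok), edgeR adjusted p = 0.0201), beat-IIIb (log2 fold change 0.86 ± 0.24), dpr16 (0.78 ± 0.14), dpr2 (0.91 ± 0.19), Nlg1 (1.52 ± 0.20) and hbs (0.49 ± 0.07) were higher, while dpr5 (-1.33 ± 0.23) and bdl (-0.56 ± 0.08) were lower. The called ligand-gated channels included GluRIIC (0.275 ± 0.117 (control) and 2.04 ± 0.272 CPM (vostok)) and GluRIIA (0.381 ± 0.153 (control) and 1.83 ± 0.385 CPM (vostok)), glutamate receptor subunits known from the neuromuscular junction. The potassium channel genes Elk (0.65 ± 0.20) and sand (1.63 ± 0.40) and the dopamine transporter gene DAT (1.16 ± 0.28) were higher. GABA-B-R2 (136 ± 50.6 (control) and 166 ± 6.41 CPM (vostok), adjusted p = 0.364) and mAChR-A (54.9 ± 21.6 (control) and 80.2 ± 8.01 CPM (vostok), adjusted p = 0.134) did not pass, although they did without control replicate 2 (adjusted p = 0.029 and 0.0112). Leaving out 1 library ended the following calls, given with the number of such libraries and the highest adjusted p: beat-IV (3; 0.0588 without vostok replicate 2), beat-IIIb (6; 0.0887 without vostok replicate 3), Elk (6; 0.108 without vostok replicate 3), sand (5; 0.0645 without vostok replicate 3) and DAT (4; 0.0605 without control replicate 3). Neuropeptide precursors were mixed: 11 of 44 tested members were higher and 4 lower (12 higher and 5 lower adjusted over the list alone; median 0.34, camera adjusted p = 0.0569). Without control replicates 1 to 4 and then vostok replicates 1 to 4 in turn, 8, 17, 9, 9, 9, 6, 4 and 6 higher and 2, 5, 3, 3, 3, 2, 2 and 2 lower genes were called. The hemocyte covariate gave 1 higher (neuropeptides). Leaving out both control libraries 1 and 3 gave 1 higher (neuropeptides). FMRFa (26 ± 3.08 (control) and 15.4 ± 1.51 CPM (vostok)) and Capa (-0.65 ± 0.11) were lower and spab (0.89 ± 0.14) higher.

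The neuronal genes differed between control libraries. The mean log2 CPM of the dpr and DIP genes was 3.88 and 3.94 in control replicates 1 and 3, but 4.89 and 4.55 in control replicates 2 and 4, against 4.80 to 4.96 in vostok libraries (exact permutation p = 0.114). Without control replicate 2, 29 of 32 dpr and DIP genes, 23 of 29 ligand-gated channels and 21 of 22 G protein-coupled receptors were higher. Without vostok replicate 2 these numbers were 2, 4 and 0. Without control libraries 1 and 3, picked after their values were seen, 5, 3 and 0 were, with medians of 0.18, 0.14 and 0.20. In control replicates 1, 2, 3 and 4 the mean log2 CPM of the hemocyte list was 6.61, 3.73, 7.75 and 6.35, and that of the imaginal disc list 4.27, 3.23, 4.19 and 3.97. The vostok libraries lay at 2.12 to 5.20 and 2.31 to 3.33.

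**Figure D2:**
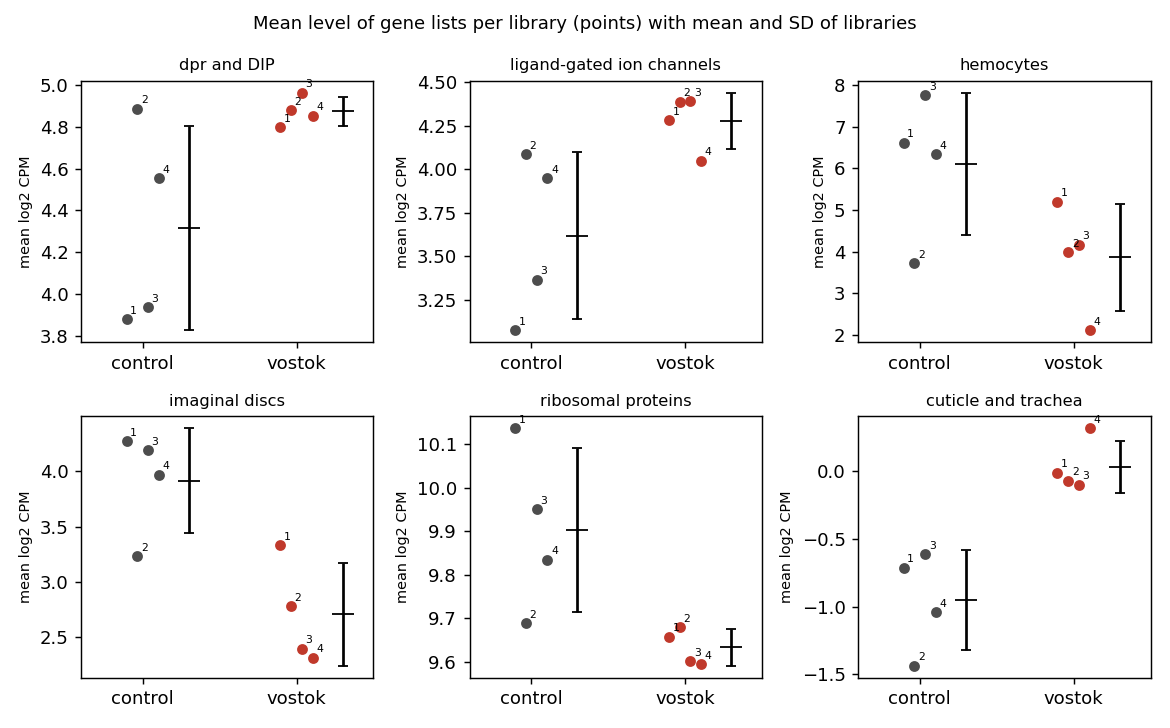
Mean log2 CPM of 6 gene lists in each library (points, numbered by replicate), with the mean ± SD of the 4 libraries of a group at the right of each set of points. Control replicate 2 lies at the vostok level for the dpr and DIP genes and the hemocyte list, whereas the groups do not overlap for the cuticle and trachea list.

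The hemocyte and imaginal disc lists passed camera in the lower direction, while the ring gland, muscle, fat body and salivary gland lists did not pass. In the hemocyte list 0 of 17 tested members were higher and 3 lower (0 higher and 10 lower adjusted over the list alone; median -2.34). Camera gave this list an adjusted p = 0.00378, and 0.677 was its adjusted p with an estimated correlation. The prophenoloxidase genes PPO1 and PPO2, made by crystal cells, were at 701 ± 618 and 1038 ± 906 CPM in control and 20.3 ± 26.3 and 51.6 ± 62.8 CPM in vostok libraries (edgeR adjusted p = 0.0265 and 0.0338), and the collagen gene vkg at 378 ± 371 (control) and 56.1 ± 35.2 CPM (vostok) (adjusted p = 0.0433). The groups overlapped for each of these 3 genes and in the list mean (exact permutation p = 0.114). Of the imaginal disc genes, 0 of 10 tested members were higher and 5 lower (0 higher and 7 lower adjusted over the list alone; median -1.45). Camera gave this list an adjusted p = 0.00535, and 0.677 was its adjusted p with an estimated correlation. The lower genes included those of the transcription factors ss (15 ± 5.3 (control) and 4.49 ± 0.392 CPM (vostok)), eyg (-1.88 ± 0.41) and ro (-1.87 ± 0.42). Ring gland genes had 4 of 9 higher (4 higher and 0 lower adjusted over the list alone; median 0.77, camera adjusted p = 0.119), with nvd, a steroid synthesis gene, at 21.5 ± 7.36 (control) and 64.4 ± 15 CPM (vostok) and the adipokinetic hormone gene Akh at 7.57 ± 2.86 (control) and 17.3 ± 1.66 CPM (vostok). The muscle list had 1 lower of 19 (0 higher and 0 lower adjusted over the list alone; median -0.40, camera adjusted p = 0.45), Zasp52 (log2 fold change -1.31 ± 0.37). Fat body genes had 2 higher of 12 (1 higher and 0 lower adjusted over the list alone; median 0.69, 0.231), with the yolk protein gene Yp1 at 0.0071 ± 0.00833 (control) and 0.543 ± 0.194 CPM (vostok). No salivary gland gene of 7 passed edgeR's test (0 higher and 0 lower at an unadjusted p below 0.05, 0 and 0 with DESeq2; 0 higher and 0 lower adjusted over the list alone; median 0.23, 0.836), and Sgs3 was at 3.85 ± 3.57 (control) and 4.51 ± 3.71 CPM (vostok). With control replicates 1 to 4 and then vostok replicates 1 to 4 left out in turn, hemocyte genes had 0, 1, 1, 0, 0, 0, 0 and 0 higher and 1, 15, 0, 1, 2, 0, 0 and 0 lower. Imaginal disc genes had 0 higher each time and 3, 7, 3, 3, 6, 2, 2 and 3 lower. Ring gland genes had 2, 4, 2, 4, 2, 3, 4 and 2 higher and 0, 2, 0, 0, 0, 0, 0 and 0 lower. Muscle genes had 0, 0, 0, 1, 0, 0, 0 and 0 higher and 0, 1, 0, 0, 0, 0, 1 and 0 lower. Fat body genes had 1, 3, 1, 2, 1, 1, 1 and 1 higher and 0, 1, 0, 0, 0, 0, 0 and 0 lower. Salivary gland genes had 0 higher each time and 0 lower each time. Under the stricter filter 0 of 9 fat body genes were higher. With the hemocyte covariate, imaginal disc genes had 1 lower and ring gland genes 1 higher. Muscle genes then had 1 higher and 0 lower, and fat body genes 1 higher. The hemocyte list itself had 1 lower, which tests nothing, because the covariate is that list's own mean. Without both control libraries 1 and 3 the calls were 1 higher and 0 lower of 18 (hemocyte), 1 lower (imaginal disc), 0 higher (ring gland), 0 lower (muscle) and 1 higher of 13 (fat body). Leaving out 1 library ended these calls, with the number of such libraries and the highest adjusted p: PPO1 (4; 0.0769 without vostok replicate 3), PPO2 (6; 0.0929 without vostok replicate 2), vkg (7; 0.11 without vostok replicate 2), Zasp52 (7; 0.0923 without vostok replicate 2) and ro (2; 0.051 without vostok replicate 2).

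Among ribosomal protein and respiratory chain genes nearly all called members were lower, by small amounts in the median. Of cytosolic ribosomal protein genes 1 of 87 tested members were higher and 31 lower (1 higher and 63 lower adjusted over the list alone; median -0.29; camera adjusted p = 4.54e-09), and of nuclear genes of oxidative phosphorylation 0 of 67 tested members were higher and 29 lower (0 higher and 45 lower adjusted over the list alone; median -0.25; camera adjusted p = 2.98e-08). RpS18 was at 1168 ± 165 (control) and 827 ± 25.1 CPM (vostok), while RpS5b, a paralog expressed in the germline, was at 6.29 ± 0.795 (control) and 16.1 ± 1.19 CPM (vostok). ND-51, a subunit of complex I, was at 129.8 ± 9.59 (control) and 102 ± 2.1 CPM (vostok), and ATPsynCF6L at 2.31 ± 0.336 (control) and 0.0398 ± 0.0184 CPM (vostok). Cell cycle genes had 7 lower of 39 (0 higher and 3 lower adjusted over the list alone; median -0.24; camera adjusted p = 0.00134), including the mitotic genes pav (-0.54 ± 0.10) and aurA (-0.42 ± 0.10). The Notch target genes of the E(spl) complex had 5 lower of 11 (0 higher and 7 lower adjusted over the list alone; median -0.56; camera adjusted p = 0.0129), among them E(spl)mgamma-HLH (59 ± 8.39 (control) and 38.3 ± 4.91 CPM (vostok)) and E(spl)m4-BFM (-0.83 ± 0.19). In control replicates 1, 2, 3 and 4 the mean log2 CPM was 10.14, 9.69, 9.95 and 9.83 (ribosomal), 6.11, 5.84, 5.91 and 5.83 (respiratory), 6.75, 6.47, 6.74 and 6.54 (cell cycle) and 5.25, 4.59, 5.02 and 4.73 (E(spl)), beside 4.27, 3.23, 4.19 and 3.97 of the imaginal disc list and 6.61, 3.73, 7.75 and 6.35 of the hemocyte list. With an estimated correlation each of these 4 lists had an adjusted p = 0.677, and fry gave 0.0935, 0.0601, 0.113 and 0.0935 in the same order. The exact permutation p of their library means, not adjusted over lists, was 0.0286, 0.0286, 0.0857 and 0.0286. For E(spl) the groups nearly touched, with control replicate 2 and vostok replicate 4 both at 4.59. RNA of the mitochondrial genome took 3.86% ± 0.705 of counts in control and 2.91% ± 0.305 in vostok libraries (SD, n = 4; exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give), a measure compared after its values were seen. Without control replicates 1, 2, 3 and 4 in turn, 22, 82, 4 and 17 ribosomal genes were lower, and without vostok replicates 1, 2, 3 and 4 in turn, 6, 4, 4 and 3. For respiratory genes these counts were 25, 40, 10 and 30, then 8, 8, 8 and 8. For cell cycle genes these counts were 3, 24, 2 and 8, then 2, 1, 2 and 6. For E(spl) genes these counts were 2, 9, 2 and 4, then 2, 1, 1 and 3. Library totals alone gave 12 lower (ribosomal) and 18 lower (respiratory). The hemocyte covariate gave 0 lower (ribosomal), 2 lower (respiratory), 0 lower (cell cycle) and 0 lower (E(spl)). Leaving out both control libraries 1 and 3 gave 4 lower (ribosomal), 13 lower of 68 (respiratory), 1 higher and 1 lower (cell cycle) and 2 lower (E(spl)). Leaving out 1 library ended these calls, with their number and the highest adjusted p: aurA (2; 0.058 without vostok replicate 2) and E(spl)m4-BFM (2; 0.058 without vostok replicate 2).

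Progenitor, identity and glial genes changed member by member. Among neuroblast and progenitor genes 3 of 19 tested members were higher and 1 lower (3 higher and 1 lower adjusted over the list alone; median 0.10, camera adjusted p = 0.291). The transcription factor genes tll (42.9 ± 5.49 (control) and 65.6 ± 3.35 CPM (vostok), edgeR adjusted p = 0.00302) and opa (0.37 ± 0.08) were higher. Among optic lobe and neuronal identity factors 10 of 56 tested members were higher and 8 lower (10 higher and 9 lower adjusted over the list alone; median 0.29). Its camera adjusted p was 0.0315, and its adjusted p with an estimated correlation 0.677. There vvl was higher (106 ± 17.5 (control) and 162 ± 9.56 CPM (vostok)) and the proneural gene ato lower (27.6 ± 8.39 (control) and 12.5 ± 1.45 CPM (vostok)). In control replicates 1, 2, 3 and 4 ato was at 37.1, 18.9, 32 and 22.6 CPM and the glial list's CG6126 at 11.4, 6.71, 14.2 and 7.85 CPM, where the optic lobe list had a mean log2 CPM of 5.82, 6.18, 5.96 and 6.14, the imaginal disc list 4.27, 3.23, 4.19 and 3.97 and the hemocyte list 6.61, 3.73, 7.75 and 6.35. The optic lobe list's camera call was lost without control replicate 1, control replicate 3 or vostok replicate 4 (adjusted p = 0.0933, 0.0872 and 0.0739). Without control replicates 1 to 4 and then vostok replicates 1 to 4 in turn, this list had 6, 26, 5, 8, 6, 4, 4 and 5 higher and 2, 10, 2, 3, 6, 1, 1 and 5 lower genes. In the same order, neuroblast genes had 2, 7, 2, 2, 2, 2, 2 and 2 higher and 1, 5, 1, 1, 1, 1, 1 and 1 lower. Glial genes had 4, 7, 3, 5, 3, 3, 3 and 4 higher and 3, 6, 3, 4, 5, 3, 3 and 3 lower. Under the stricter filter 5 optic lobe and identity genes were lower. Fitted with the hemocyte covariate, the calls were 1 higher and 0 lower (optic lobe and identity), 1 higher and 0 lower (neuroblast) and 2 higher and 3 lower (glial). Without both control libraries 1 and 3 the calls were 5 higher and 1 lower (optic lobe and identity), 1 higher (neuroblast) and 3 lower (glial). Among glial genes 5 of 25 tested members were higher and 6 lower (5 higher and 7 lower adjusted over the list alone; median 0.06, mean -0.03, camera adjusted p = 0.739): zyd, a sodium/calcium exchanger gene of glia, was at 84.8 ± 7.89 (control) and 149.6 ± 4.81 CPM (vostok), the blood-brain barrier transporter gene Mdr65 at 88.7 ± 6.24 (control) and 55.4 ± 3.44 CPM (vostok), and CG6126 at 10.1 ± 3.43 (control) and 3.29 ± 0.636 CPM (vostok) (adjusted p = 2.47e-04, 4.9e-04 and 0.00438).

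Stress, immune and metabolic genes showed changes of both signs. Among cell death and DNA damage genes 6 of 25 tested members were higher and 6 lower (6 higher and 6 lower adjusted over the list alone; median -0.03, mean 0.17, camera adjusted p = 0.527), with Gadd45 (7.6 ± 1.97 (control) and 18.9 ± 3.05 CPM (vostok)), Ets21C (1.16 ± 0.20) and upd1 (0.87 ± 0.13) higher. Of heat shock genes, 3 of 17 tested members were higher and 2 lower (4 higher and 2 lower adjusted over the list alone; median 0.27, camera adjusted p = 0.169): Hsp22 was at 4.27 ± 1.32 (control) and 20.3 ± 5.99 CPM (vostok) and Hsp27 at 2131 ± 142 (control) and 1790.2 ± 66.1 CPM (vostok). Of immune genes, 7 of 19 tested members were higher and 7 lower (8 higher and 7 lower adjusted over the list alone; median -0.18, mean -0.08, camera adjusted p = 0.585 in the higher direction); Bbd was at 2.28 ± 0.798 (control) and 16.5 ± 1.72 CPM (vostok) and Tep2 at 68.7 ± 12.9 (control) and 35 ± 3.4 CPM (vostok). Detoxification enzymes had 15 higher and 32 lower of 101 (19 higher and 35 lower adjusted over the list alone; median -0.34). Camera gave this list an adjusted p = 0.0262, and 0.677 was its adjusted p with an estimated correlation. Its mean log2 CPM in control replicates 1, 2, 3 and 4 was 1.45, 1.00, 1.62 and 1.15, beside 6.61, 3.73, 7.75 and 6.35 of the hemocyte list. Beside the P450 genes given above, Cyp28d1 was at 25.8 ± 6.75 (control) and 0.663 ± 0.208 CPM (vostok). The camera call was lost without control replicate 1, control replicate 3 or vostok replicate 2 (adjusted p = 0.16, 0.18 and 0.0791). Library means of the cell death list were higher in vostok libraries without overlap (exact permutation p = 0.0286, not adjusted over lists). As control replicates 1 to 4 and then vostok replicates 1 to 4 were left out in turn, cell death genes had 4 to 8 higher and 3, 8, 1, 5, 1, 1, 2 and 2 lower. Heat shock genes had 3, 5, 2, 2, 2, 2, 2 and 3 higher and 1, 3, 1, 1, 0, 0, 0 and 0 lower. Immune genes had 7 to 9 higher and 5 to 6 lower. Detoxification genes had 17, 26, 15, 18, 11, 11, 9 and 11 higher and 25 to 45 lower. Library totals alone gave 0 lower (heat shock). The stricter filter gave 4 higher and 4 lower of 9 (immune) and 6 higher of 57 (detoxification). The hemocyte covariate gave 3 higher and 0 lower (cell death), 0 lower (heat shock), 4 higher and 2 lower (immune) and 9 higher and 20 lower (detoxification). Leaving out both control libraries 1 and 3 gave 3 higher and 1 lower (cell death), 1 lower (heat shock) and 4 lower of 23 (immune). The median of the immune list was 0.07, 1.06 and 0.49 without control replicates 1, 3 and 4. The Hsp27 call was lost with upper quartile factors (adjusted p = 0.0517) or library totals (0.063), though not with RLE factors, and when any of 5 libraries was left out (highest adjusted p 0.0831, vostok replicate 4 left out).

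Genes of timing, germline and sex gave smaller lists. Ecdysone response genes had 7 higher and 2 lower of 22 (8 higher and 2 lower adjusted over the list alone; median 0.30). Its camera adjusted p was 0.0393, and its adjusted p with an estimated correlation 0.677. ImpE1 was at 178 ± 16.2 (control) and 287 ± 54.8 CPM (vostok), and Kr-h1 had a log2 fold change of 0.32 ± 0.07. The ecdysone list had a mean log2 CPM of 5.28, 5.59, 5.47 and 5.50 in control replicates 1, 2, 3 and 4, where the hemocyte list had 6.61, 3.73, 7.75 and 6.35. Without control replicate 1, control replicate 3 or vostok replicate 1 the camera adjusted p was 0.0933, 0.0516 and 0.0752. Clock genes had 3 higher and 1 lower of 9 (3 higher and 1 lower adjusted over the list alone; median 0.27, camera adjusted p = 0.097). The blue light receptor gene cry was at 1.2 ± 0.541 (control) and 4.74 ± 0.286 CPM (vostok) (edgeR adjusted p = 0.00312), cyc at 39.2 ± 0.72 (control) and 47.4 ± 2.6 CPM (vostok) and vri at 145 ± 22.1 (control) and 206 ± 21.7 CPM (vostok). The vri call was lost without control replicate 3 or vostok replicate 2 (highest adjusted p 0.0562). Library means of the clock list were higher in vostok libraries without overlap (exact permutation p = 0.0286, not adjusted over lists). Germline genes had 5 higher and 3 lower of 23 (5 higher and 3 lower adjusted over the list alone; median -0.06, mean 0.17, camera adjusted p = 0.696), with dhd at 0.0275 ± 0.0163 (control) and 0.665 ± 0.261 CPM (vostok) and bam at 0.385 ± 0.135 (control) and 1.26 ± 0.164 CPM (vostok). In fits without control replicates 1 to 4 and then vostok replicates 1 to 4 in turn, ecdysone response genes had 3, 11, 2, 3, 4, 2, 2 and 6 higher and 0, 2, 0, 0, 3, 0, 0 and 0 lower. Clock genes had 3, 5, 2, 3, 3, 2, 3 and 3 higher and 1, 1, 0, 0, 0, 0, 0 and 0 lower. Germline genes had 4, 7, 4, 5, 4, 3, 4 and 5 higher and 2, 5, 1, 3, 2, 0, 0 and 2 lower. Male-specific RNA genes had 0, 3, 0, 0, 0, 0, 0 and 0 higher and 0 lower each time. Scaled by library totals alone, 1 ecdysone response gene was lower. Under the stricter filter 1 of 19 ecdysone response genes was lower and 3 of 14 germline genes were higher. Fitted with the hemocyte covariate, the calls were 1 higher and 0 lower (ecdysone response), 1 higher and 0 lower (clock) and 0 lower (germline). Without both control libraries 1 and 3 the calls were 2 higher and 0 lower (ecdysone response), 0 lower (clock) and 3 higher and 0 lower of 24 (germline). None of 3 male-specific RNAs passed edgeR's test (1 higher and 0 lower at an unadjusted p below 0.05, 1 and 0 with DESeq2; 0 higher and 0 lower adjusted over the list alone; median 0.61, camera adjusted p = 0.181); lncRNA:roX1 was at 982 ± 452 (control) and 1499 ± 426 CPM (vostok) and msl-2 at 66.8 ± 12.2 (control) and 84.1 ± 13.4 CPM (vostok), and both passed without control replicate 2 (adjusted p = 0.0115 and 0.0278).

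Calls among genes for chromosome architecture depended on the tool and on single libraries. Of 26 architectural protein genes, insulator-binding proteins and cohesin with its loaders, 0 were higher and 2 lower in edgeR's test (0 higher and 0 lower adjusted over the list alone; median 0.04, mean -0.00, camera adjusted p = 0.935). There were 3 higher and 4 lower at an unadjusted p below 0.05, and with DESeq2 3 and 4. The lower ones with edgeR were Ibf1 (31.9 ± 3.16 (control) and 25.5 ± 1.13 CPM (vostok), edgeR adjusted p = 0.0198) and dwg (29.4 ± 1.45 (control) and 25.7 ± 1.24 CPM (vostok), 0.0417). Polycomb group genes had 0 higher and 1 lower of 16 in edgeR's test (0 higher and 0 lower adjusted over the list alone; median 0.11, camera adjusted p = 0.15), esc (-0.22 ± 0.06, adjusted p = 0.0338). Of their fold changes 14 were positive. Of these genes 6 were higher and 1 lower at an unadjusted p below 0.05, and 4 and 1 with DESeq2. There were 6 higher and 1 lower without control replicate 2. In edgeR fits that left out control replicates 1 to 4 and then vostok replicates 1 to 4, architectural genes had 0, 1, 0, 0, 0, 0, 0 and 0 higher and 1, 3, 1, 1, 0, 1, 0 and 0 lower. Polycomb group genes had 0, 6, 0, 0, 0, 0, 0 and 0 higher and 0, 1, 0, 0, 0, 0, 0 and 1 lower. Hox genes had 1, 2, 1, 1, 1, 1, 1 and 1 higher and 0, 3, 0, 0, 1, 0, 0 and 0 lower. Library totals alone gave 1 lower (architectural) and 0 lower (Polycomb group). The stricter filter gave 1 higher and 1 lower (architectural). The hemocyte covariate gave 0 lower (architectural), 0 lower (Polycomb group) and 0 lower (Hox). Leaving out both control libraries 1 and 3 gave 1 lower (architectural), 0 lower (Polycomb group) and 0 lower (Hox). Of 8 Hox genes, abd-A (FBgn0000014; 3R, 16807214 to 16830049) was higher at 46.3 ± 6.44 (control) and 92.3 ± 9.38 CPM (vostok) (log2 fold change 1.00 ± 0.11, adjusted p = 8.71e-04), a call that held with any 1 library left out, and lab was lower at 2.37 ± 0.396 (control) and 1.47 ± 0.259 CPM (vostok) (adjusted p = 0.037); the list's median was 0.07 and its mean -0.01 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.637). Leaving out 1 library ended these calls, with the number of such libraries and the highest adjusted p: Ibf1 (3; 0.0601 without vostok replicate 3), dwg (7; 0.11 without vostok replicate 3), esc (6; 0.10 without vostok replicate 2) and lab (6; 0.103 without vostok replicate 2). The calls of dwg and esc ended too with upper quartile factors (adjusted p = 0.0763 and 0.0574) or library totals (0.11 and 0.0627), though not with RLE factors.

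Changed genes lay on all 6 chromosome arms. On X 430 of 1800 tested genes changed (23.9%), against 29.2% on the other arms (odds ratio 0.76, 95% interval 0.674 to 0.856; Fisher's exact test, two-sided, adjusted over 6 arms p = 2.29e-05). The shares on 2L, 2R, 3L, 3R and 4 were 30.3%, 30.1%, 30%, 27.3% and 23.2%, none past the threshold (adjusted p = 0.0792 to 0.304). 3 arms passed when control replicate 1, control replicate 3, control replicate 4, vostok replicate 1, vostok replicate 3 or vostok replicate 4 was left out. Within 1 Mb of CG11504 on 3R, 69 of 199 genes changed (34.7%), against 26.6% of the rest of the arm (odds ratio 1.46, 95% interval 1.06 to 2.0, exact p = 0.0163). The difference did not pass within 0.25 Mb (odds ratio 1.19, exact p = 0.519), within 3 Mb (1.17, exact p = 0.185) or without control replicate 2 (1.28, exact p = 0.104). Neighbouring tested genes both changed in 959 pairs, where shuffling the calls within arms gave 863 (ratio 1.11, permutation p = 1e-04, the smallest that 10000 shuffles can give). In 67.5% of these pairs both genes moved the same way, against 51.1% in shuffles (permutation p = 1e-04, again the smallest possible). Fisher's test takes genes as independent, which such neighbours are not. Its p-values for arms and for the surroundings of CG11504 may thus be too small, and its intervals too narrow. Pairs at least 1 kb apart numbered 430 against 286 in shuffles, and closer or overlapping pairs 529 against 577 (two-sided permutation p = 0.012). At the rates of change of their own genes, 34.2% and 25.4%, 414 distant and 462 closer pairs would both change. The pairs include copies that lie side by side.

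**Figure D3:**
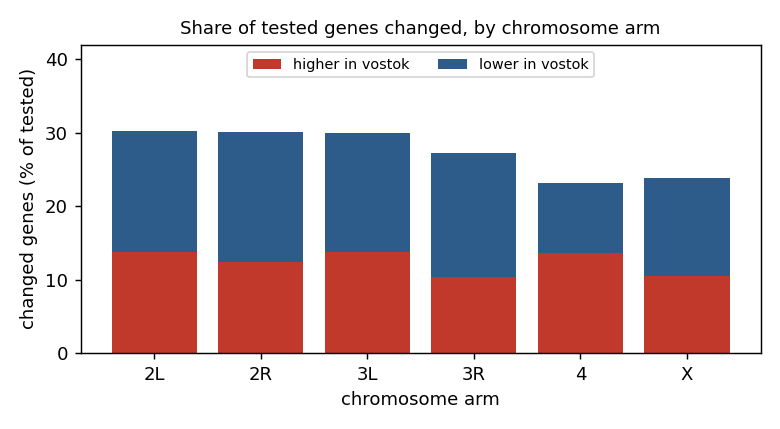
Percentage of tested genes on each chromosome arm that were higher (red) or lower (blue, stacked) in vostok libraries at an adjusted p below 0.05. The bar of X is lower than those of 2L, 2R and 3L.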

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

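The tests of other tissue, of single libraries, of even background, of linked segments and of strain, and the sums per element family, were chosen after the result was seen; the splits of the libraries, gene span and depth were set before. Only the real split of the 8 libraries, 1 of 35, gave 3040 changed genes, 1299 higher, 1741 lower or 1233 changed at least 2-fold. The other splits gave at most 1, but each of them mixes the groups, which by itself lowers the calls. A share of 1 in 35, or 0.0286, is the smallest possible, so this comparison does not exclude chance for these 4 counts. They are parts of 1 result. The number of gene lists did not single out the real split: 13 of the 35 splits passed 19 lists or more, up to 23. This points to a structure among the libraries that moves many lists together.

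The pooled 221 genes of 7 neuronal lists had a median log2 fold change of 0.48. If other tissue diluted brain RNA in control libraries, glial and neuroblast genes were predicted to be higher by as much. The neuronal median exceeded theirs by 0.38 (95% interval over genes 0.23 to 0.48, genes not being independent replicates). This does not decide against dilution, because other tissue may hold glial and neuroblast RNA too, which was not tested. From control replicate 1 to control replicate 2 the neuronal mean log2 CPM rose from 4.99 to 5.98, while the hemocyte mean fell from 6.61 to 3.73. Over the same libraries the neuroblast mean moved only from 5.85 to 5.93 and the glial mean from 5.77 to 5.95. Dilution that lowers all brain RNA alike would have moved these means with the neuronal mean. What set control replicates 1 and 2 apart was not tested. A trend with gene span is argued against as the whole cause, since the median after its removal was 0.37 (95% interval over genes 0.36 to 0.43). Differences of composition or age between single libraries, apart from genotype, stay open: the control libraries spanned 1.95 times the group difference in mean log2 CPM, and the groups overlapped (exact permutation p = 0.114). An effect of the mutation on neurons stays open too.

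Genes of the cuticle, gut and chemosensory lists were more often higher than lower in vostok libraries, 50 of 128 higher and 12 lower, and 40 and 4 of the 82 under 1 CPM. Other genes under 1 CPM leaned the same way (442 and 103) by less (median log2 fold change 0.44, against 1.46; difference 1.02, 95% interval over genes 0.18 to 1.90, among genes that passed the filter), while at or over 1 CPM 817 genes were higher and 1634 lower. Depth is argued against: thinned to the same total, the lowest vostok library still held 369 more genes with at least 10 counts than the highest control library. An even background would lift every silent gene alike. The 363 list genes under 1 CPM in control, taken without filter or test, gained a median of 0.0155 CPM and a mean of 0.15 (95% interval over genes 0.102 to 0.211). The criterion, that their upper quartile, 0.0986, lie below that interval, was met by a narrow margin. It was set with the median and quartile known, so this test does not decide against an even background. Earlier forms of this test, on filtered and on called genes, were set aside because selection favoured their outcome. Small pieces of other tissue, strain and the mutation were not separated by a test and may each contribute.

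By fitted fold 168 genes changed at least 16-fold, 128 higher and 40 lower. With levels under the floor set to it there were 106, 67 higher and 39 lower. The 168 genes could stem from a segment carried along with the CG11504 mutation. The map argues against this as the whole cause: 35 lay on 3R, 3 of them within 1 Mb, with an odds ratio of 0.81 against the other arms (95% interval 0.54 to 1.19; 0.716 with the floor). A strain difference elsewhere in the genome and the mutation cannot be told apart, because the labels give no second stock of either genotype. A y allele of a control stock named yw could account for y, which lies on X and had a log2 fold change of 7.18.

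Transposable element rows lie outside the gene comparison. Summed per family and tested with edgeR, 9 entries at 5 CPM or more were at least 4-fold higher in vostok libraries with an adjusted p below 0.05 and separate groups, here as mean CPM ± SD in control and vostok libraries: S (18.2 ± 3.71 and 264 ± 13.4), HeT-A (28.1 ± 8.14 and 373 ± 20.5), RR51475 (9.12 ± 1.3 and 88.3 ± 18.8), HMS-Beagle (60 ± 11.9 and 321 ± 12.5), gypsy5 (3.63 ± 0.629 and 31.7 ± 1.99), Stalker2 (24.8 ± 3.09 and 113 ± 15.2), RR48344 (3.72 ± 1.2 and 38.7 ± 3.63), hopper (1.95 ± 0.823 and 9.84 ± 1.58) and RR51007 (1.94 ± 0.869 and 9.32 ± 1.43). Those whose names begin with RR are single repeat entries, not families. By the same limits 4 entries were lower: Idefix (22.2 ± 11.3 and 5.2 ± 1.0), RR48304 (6.9 ± 8.39 and 0 in each vostok library), Tabor (18.6 ± 5.72 and 3.97 ± 0.705) and TART-C (28.9 ± 2.94 and 0.147 ± 0.0635). HeT-A and the TART entries are elements of fly telomeres. TART-C, like the RR entries, is a single entry, so its fall is not that of a family summed over copies.

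A single library stood far from the other 3 of its group in 15 of 284 sets of 4 values, close to the 14.2 that chance gives at 1 in 20. These were Cyp6a17 at 15.8 CPM in vostok replicate 3 (others 12.3 to 12.7), CR43216 at 13.6 CPM in control replicate 4 (others 5.32 to 6.32), CR43216 at 0.0692 CPM in vostok replicate 4 (others 0), Sdic3 at 0.0833 CPM in vostok replicate 1 (others 0), CR42653 at 0.161 CPM in vostok replicate 2 (others 0), CG15824 at 7.02 CPM in vostok replicate 3 (others 5.71 to 5.92), sand at 0.285 CPM in control replicate 4 (others 0.0864 to 0.112), ND-51 at 98.4 CPM in vostok replicate 1 (others 102 to 103), PPO1 at 59.4 CPM in vostok replicate 1 (others 2.51 to 10.4), PPO2 at 145 CPM in vostok replicate 1 (others 9.1 to 26.4), Akh at 11.9 CPM in control replicate 4 (others 5.91 to 6.35), Sgs3 at 9.2 CPM in control replicate 4 (others 1.79 to 2.26) and Cpr65Ec at 7.11 CPM in vostok replicate 3 (others 8.53 to 8.75). The salivary gland list had a mean log2 CPM of 1.09 in control replicate 4 (others -0.94 to -0.77), and ribosomal RNA took 8.11% of the counts of vostok replicate 3 (others 0.797 to 1.41%).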

How the results depend on the processing

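The covariate, the fit without control libraries 1 and 3, the fit without ribosomal and mitochondrial RNA genes and the gap of 1 kb were chosen after the data were seen. No call of the 102 named genes reversed: of 2240 values under the alternatives 2015 stayed on their side of the threshold, 218 were no longer past it and 7 came to pass it, 4 further ones could not be computed, and 63 genes kept their side in each setting. With 1 library left out the changed genes numbered 1521 to 5333, the higher 779 to 2523, the lower 736 to 2810 and those changed at least 2-fold 881 to 1805; fewer libraries lower the power, but leaving out control replicate 2 raised the count. glmTreat gave 1385 changed (751 higher, 634 lower), an adjusted p below 0.01 1057 (602, 455; 689 at least 2-fold), the hemocyte covariate 1019 (622, 397; 688) and the fit without control libraries 1 and 3 1593 (701 lower; 809). The higher genes numbered 2010 with DESeq2 and 1969 with voom quality weights, and 655 genes changed at least 2-fold under the stricter filter, which tests fewer genes. The other alternatives, the replicate block apart, stayed within 1.5 times. The cause of these differences was not tested.

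With a replicate block 1564 genes changed (804 higher, 760 lower). Whether the numbers pair the libraries is not stated in the labels and stays open. The correlations of same-numbered deviations were 0.18, 0.00712, 0.0388 and -0.0473. No vostok library correlated best with the control library of its own number, and of the control libraries only replicate 1 correlated best with its own number. The highest correlation, 0.311, was that of control replicate 3 with vostok replicate 1. Under the block 3 ribosomal and 5 respiratory genes were lower, and 4 cell death genes were higher and 0 lower. The block passed the male-specific list (adjusted p = 0.0254) and 2 arms.

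An estimated correlation passed 0 lists, fry 4, the hemocyte covariate 5 and the fit without control libraries 1 and 3 8, against 19. Adjusted p-values of lists that changed side were, with an estimated correlation, beat and side, dpr and DIP, axon guidance, ligand-gated ion channels, voltage-gated and leak channels, G protein-coupled receptors, synapse and mature neuron, E(spl) complex, optic lobe and identity factors, cell cycle, detoxification enzymes, ecdysone response and timing, ribosomal proteins, oxidative phosphorylation, hemocytes, imaginal discs 0.677, cuticle and trachea, gut enzymes, chemoreceptors 0.534. With fry they were beat and side, dpr and DIP, G protein-coupled receptors, optic lobe and identity factors, cell cycle 0.113, axon guidance 0.123, ligand-gated ion channels 0.0832, voltage-gated and leak channels 0.151, synapse and mature neuron 0.154, E(spl) complex, detoxification enzymes, ribosomal proteins 0.0935, ecdysone response and timing, oxidative phosphorylation, imaginal discs 0.0601, germline genes 0.0474, hemocytes 0.132. With the hemocyte covariate they were beat and side 0.267, dpr and DIP 0.221, axon guidance 0.265, ligand-gated ion channels, E(spl) complex, detoxification enzymes, imaginal discs 0.114, voltage-gated and leak channels 0.859, G protein-coupled receptors 0.325, synapse and mature neuron 0.972, optic lobe and identity factors 0.637, cell cycle 0.109, ecdysone response and timing 0.175, ring gland 0.0176, chemoreceptors 0.15. Without control libraries 1 and 3 they were beat and side, E(spl) complex 0.0571, axon guidance 0.128, voltage-gated and leak channels 0.619, G protein-coupled receptors 0.0671, synapse and mature neuron 0.622, optic lobe and identity factors 0.30, cell cycle 0.0815, detoxification enzymes 0.57, ecdysone response and timing 0.159, hemocytes 0.229. Library totals alone gave optic lobe and identity factors 0.0838, ecdysone response and timing 0.106, and the stricter filter neuropeptides 0.0327, chemoreceptors 0.0747. With 1 library left out, lists that changed side had adjusted p-values of 0.00275 to 0.213 (neuropeptides), 0.0161 to 0.0933 (optic lobe and identity factors), 0.00497 to 0.18 (detoxification enzymes), 0.0207 to 0.0933 (ecdysone response) and 0.0292 to 0.463 (ring gland). The median of the chemoreceptor list turned to -0.33 under the stricter filter. The cause was not tested.

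X had fewer changed genes under each alternative run (odds ratio 0.683 to 0.871). The number of arms past the threshold was 4 with DESeq2 and 1 to 3 with 1 library left out. Near CG11504 the odds ratio was 1.28 to 1.8 with 1 library left out, and it did not pass with DESeq2 (1.23, exact p = 0.173) or in windows of 0.25 Mb (1.19) and 3 Mb (1.17). The excess of neighbouring changed pairs passed under each alternative run (ratio 1.04 to 1.9). Depth limits genes near the floor. In the simulation, whose settings differ from these data, 37.9% of 1.5-fold changes were recovered, so uncalled small changes are not shown to be absent.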

Other observations

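The tests of element families, of neighbours at least 1 kb apart and of closer ones were chosen after the results were seen. Transposable element rows took a larger share of counts in vostok libraries, 0.659% ± 0.0226 against 0.527% ± 0.0313 (SD, n = 4; exact permutation p = 0.0286, the smallest possible). Of 134 families and single repeat entries tested with edgeR, 30 were higher and 16 lower. For HeT-A, TART-A, TART-B and TART-C the sums covered 27, 10, 3 and 1 entries. Of the telomeric entries HeT-A, TART-A and TART-B were higher and TART-C lower: TART-A was at 4.01 ± 1.73 CPM in control and 12 ± 0.781 CPM in vostok libraries (adjusted p = 0.00331), TART-B at 0.0282 ± 0.0209 CPM in control and 0.577 ± 0.0689 CPM in vostok libraries (adjusted p = 1.29e-04) and TART-C at 28.9 ± 2.94 CPM in control and 0.147 ± 0.0635 CPM in vostok libraries (adjusted p = 1.1e-09). Among retrotransposons, copia was at 994 ± 67 CPM in control and 1511 ± 132 CPM in vostok libraries, 3S18 at 925 ± 87.6 CPM in control and 520.0 ± 35.6 CPM in vostok libraries, Tabor at 18.6 ± 5.72 CPM in control and 3.97 ± 0.705 CPM in vostok libraries and the I element at 36.9 ± 5.91 CPM in control and 98.3 ± 11.8 CPM in vostok libraries, a choice made after their values were seen. A general release of elements in the mutant is a hypothesis that these data leave undecided: 65.2% of the changed entries were higher (exact binomial 95% interval 49.8% to 78.6%, p = 0.0541). Different insertions in the stocks may give the same values, and reads cannot be assigned to single copies of a family with certainty.

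Neighbouring genes that both changed were in excess of shuffles within arms only where the genes lay at least 1 kb apart: 430 pairs against 286 in shuffles (ratio 1.5, permutation p = 1e-04, the smallest possible), against a ratio of 0.917 in closer pairs. Of the genes in distant pairs 34.2% changed, and of those in closer pairs 25.4%. At these rates 414 distant and 462 closer pairs would both change, so most of the distant excess may come from the higher rate of change among genes far from their neighbours, and closer pairs exceed the number at their own rate. Both genes moved the same way in 66.3% of the distant and 68.4% of the closer pairs, against 51.1% and 51.2% in shuffles (permutation p = 1e-04 for each, the smallest possible). Gene copies that lie side by side were not removed.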
